A study of Mus musculus with 12 samples.

How the data were processed

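RNA of sorted eosinophils was measured in 12 libraries from 5 mice, with 4 libraries from blood, 4 from gonadal and 4 from subcutaneous adipose tissue. Libraries were made, per the labels, with a SMARTer stranded total RNA kit for low input. Total RNA libraries of this kind also hold unspliced and non-coding transcripts, including mitochondrial ribosomal RNA. Per the submitters' processing notes, Trim Galore 0.6.4, Salmon 1.6.0 and DESeq2 1.30.1 were used, with the mm10 build. Each deposited table lists 140992 transcripts with estimated counts, TPM and effective lengths, per the file headers. The authors' estimated counts need not be whole, because Salmon divides a read among the transcripts it fits. The deposited TPM values were used only as weights for the effective transcript length of a gene. The effective length, another deposited quantity, entered only as an alternative length offset. The annotation release behind the tables is not given in the sources used here.

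Transcripts were assigned to genes with the GENCODE M21 annotation of GRCm38, the assembly of mm10. Ignoring version numbers, 139791 transcripts matched and 1201 did not. The unmatched ones held 0.351% to 0.538% of the reads of a library and stayed out of library sizes and tests. The expected counts were summed over the transcripts of each of 54115 genes and rounded to whole numbers. Coordinates come from that annotation. Genes that share reads with near-identical copies are uncertain at the level of the copy. This concerns Hspa1a, the Ear genes, the Bcl2a1 genes, the haemoglobin genes and the MHC genes among those named. Whether strand was used in quantification is not given in the sources used here, so reads of overlapping antisense genes may be mixed.

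Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust settings, TMM normalization, filterByExpr by group). All 12 libraries entered 1 fit, with the group as the only term. This left 15367 genes, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The common biological coefficient of variation was 0.545. CPM values were computed with TMM-scaled library sizes, and errors are SD over 4 libraries unless called SE. The SE of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F statistic. Folds against a group with 0 counts are lower bounds from a floor of 3 counts over the group. For 1 to 3 counts an exact 95% interval of the count ratio is given. Floors and intervals cover counting error only. Libraries were made by PCR without molecular identifiers that the labels name, so reads are not independent molecules. The depth ranged from 4379954 to 23734940 estimated reads, so the shallowest library gives the least precise value for a gene of low abundance.

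Before the data were examined, 18 functional gene lists and 16 lists of markers of other cells were written down with 736 symbols, of which 1 did not match a gene. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. The test was repeated with an estimated correlation. P-values were adjusted within each kind of list and comparison. Some genes stand on several lists, such as Vegfa and Ltb. The other-cell genes Cxcr2, Mmp8, Ccr2 and Fn1 also stand on functional lists, and how many other-cell genes eosinophils express themselves was not counted. With all libraries and no block, setting genes without reads in a group at their bound left the list medians as they were. The genes named in the text follow a rule fixed at the same time. It takes the 8 largest changes in each direction with a mean of at least 20 CPM in the higher group and no overlap between libraries, leaving out predicted genes, immunoglobulin and T cell receptor segments, mitochondrial, ribosomal and small RNA genes, ribosomal protein genes and other-cell genes. It adds up to 2 called members of each functional list with the largest change in the main direction and 1 in the other, also of at least 20 CPM, the 2 most abundant members of each other-cell list, and Ptprc, Itgam, Siglecf, Adgre1, Prg2, Epx, Ccr3 and Il5ra. S100a8 was added after its values were seen. Medians, means and camera directions differed in sign only for lists that were not called with all libraries.

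Mouse numbers in the labels mark the animal, so samples with the same number are paired. The correlation of deviations from group means was -0.11 to 0.358 over 9 same-mouse pairs. Their mean was 0.0842, against -0.0188 for pairs of different mice across groups. The model without mouse was fixed as the main one, and a model with mouse as a block was an alternative. The consensus correlation from duplicateCorrelation was 0.085. No sequencing batch is named in the labels, and none could be checked.

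Alternatives fixed before the data were examined were mouse as a fixed or random effect, DESeq2 1.42.0, limma-voom with sample weights and other scalings. Further ones were other count filters, fits on 8 libraries, a length offset, gene classes taken out, a fold change limit and leaving out each library in turn. Leaving out both the subcutaneous library of mouse 2846 and the blood library of mouse 2807, and the tests of lists and gene families without each library in turn, were chosen after seeing the data. The fit was tested on simulated counts with the real genes' means and library sizes and 200 changed genes. For gonadal adipose against blood, 54.3% of 94 genes changed 4-fold and 12.6% of 95 genes changed 2-fold were recovered with 14779 genes tested. For subcutaneous adipose against blood, 51.6% of 95 and 14.6% of 96 genes were recovered with 14755 genes tested. For the depots, 50% of 98 and 15.2% of 99 genes were recovered with 14847 genes tested. Shared controls were simulated 20 times. Within groups every pair of libraries differed by more than sampling noise, with a chi-square per gene of at least 48.1. Single measures were compared with exact permutation tests in Python 3.11.15 with scipy 1.17.1. TPM values were not tested as a level.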

Results

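The series profiled RNA from eosinophils of blood and of 2 fat depots in mice. Eosinophils are granulocytes that circulate briefly and settle in tissues, including fat. The 12 libraries came from 5 male FVB/NJ mice aged 20 weeks and fed chow. They formed 3 groups of 4: blood (mice 2807, 2771, 2683 and 2668), gonadal adipose tissue (mice 2846, 2807, 2683 and 2668) and subcutaneous adipose tissue (mice 2846, 2807, 2771 and 2668). The cells had been sorted as live leukocytes carrying CD45, CD11b and Siglec-F. Per the labels, the fat samples were digested with collagenase II at 37 C for 45 min before sorting, and no digestion is given for blood.

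The deposited values were estimated read counts per transcript, summed here per gene. The subcutaneous library of mouse 2846 held 4379954 estimated reads, and the other libraries held 12477671 to 23734940. In that library 28.0% of reads came from mitochondrial ribosomal RNA, against 4.64% to 8.74% in the others. It also stood apart on the second principal component, with a score of 147.4, while the other subcutaneous libraries scored from -44.4 to -22.4. On the first component, which carried 43.5% of the variance, all blood libraries lay below 0 and all adipose libraries above 0. The blood library of mouse 2807 lay nearest to adipose at -80.9, and the other blood libraries lay between -140.2 and -114.8. Haemoglobin genes took 0.827% of reads in the blood library of mouse 2771, against 0.00192% to 0.0145% in the other blood libraries.

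**Figure D1:**
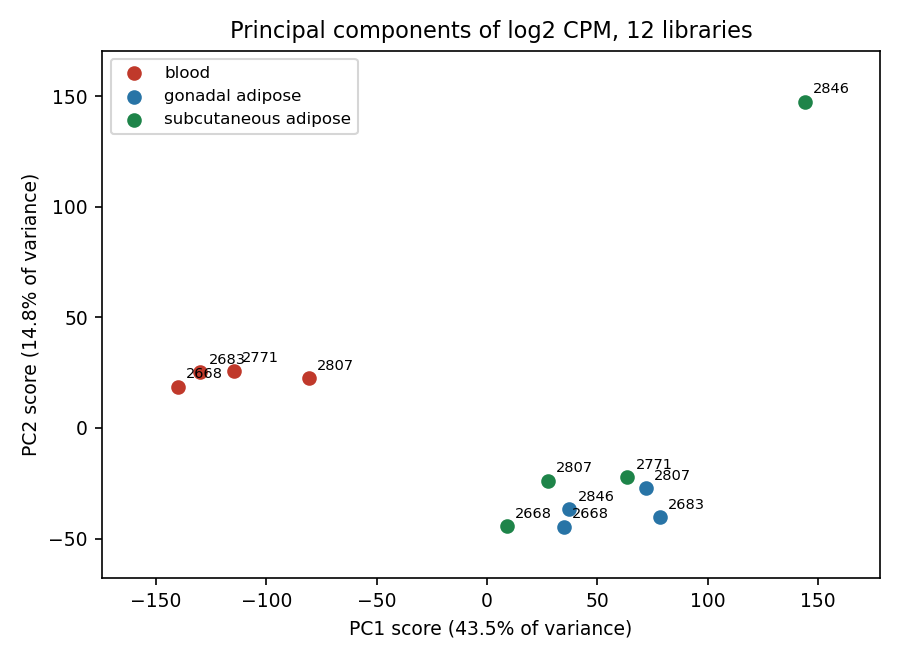
Scores of the 12 libraries on the first principal component (horizontal, 43.5% of variance) and the second (vertical, 14.8%), computed from log2 CPM of the genes tested; each point is a library, coloured by group and marked with its mouse number. Blood lies between -140.2 and -80.9 on the horizontal axis, and the subcutaneous library of mouse 2846 lies at 147.4 on the vertical axis.

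The first comparison asked how eosinophils resident in gonadal fat differ from those in blood. Early response genes stood far higher in gonadal adipose, and so did many cytokine and chemokine genes (for that list, adjusted p = 0.159 with an estimated correlation). Cxcl2, a neutrophil-attracting chemokine (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938 in mm10), had a mean of 430.3 ± 64.3 CPM in gonadal adipose and 0.702 ± 0.167 CPM in blood (SD, n = 4 each). Its log2 fold change was 9.24 (SE 0.322). Nr4a3, a nuclear receptor induced early on stimulation, rose by 9.46 (SE 0.71) on the log2 scale, and Hspa1a, a heat shock protein, by 9.49 (SE 0.778). Vegfa, which drives vessel growth, rose 92.6-fold, from 4.34 ± 0.937 to 402.7 ± 211 CPM (SD, n = 4 each). The eosinophil-associated ribonuclease genes Ear1, Ear6 and Ear10 and the G-CSF receptor gene Csf3r were lower in gonadal adipose. Csf3r had 325.1 ± 96.5 CPM in blood and 11.1 ± 3.39 CPM in gonadal adipose (SD, n = 4 each), a log2 fold change of -4.87 (SE 0.391).

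Of the 34 measured genes on the immediate early and dissociation response list, 31 rose in gonadal adipose and none fell (33 rose adjusted over the list alone), with a median log2 fold change of 2.92. The list was called by camera (adjusted p = 1.66e-22) and with an estimated correlation (adjusted p = 0.000806). On the NF-kB and TNF response list 16 of 27 genes rose and 1 fell (18 and 1 adjusted over the list alone). Its adjusted p was 4.07e-09, and 0.0367 with an estimated correlation. The latter lay between 0.0507 and 0.0698 without the blood library of mouse 2771, the gonadal library of mouse 2846, 2807 or 2683 or the subcutaneous library of mouse 2807 or 2668. The dendritic cell activation marker Cd83 rose by 6.73 (SE 0.904) on the log2 scale, and by 7.60 without the blood library of mouse 2807. Tnfaip3, an inhibitor of NF-kB signalling, rose by 4.42 (SE 0.353), and Tnip1 had -0.96 (SE 0.141). Among 31 cytokine and chemokine genes, 21 rose and 2 fell, the same counts when adjusted over the list alone, with a median of 4.56. That list's adjusted p was 4.77e-07, and 0.159 with an estimated correlation (0.0427 without the subcutaneous library of mouse 2846). The lymphotoxin gene Ltb had a log2 fold change of -2.91 (SE 0.283).

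**Figure D2:**
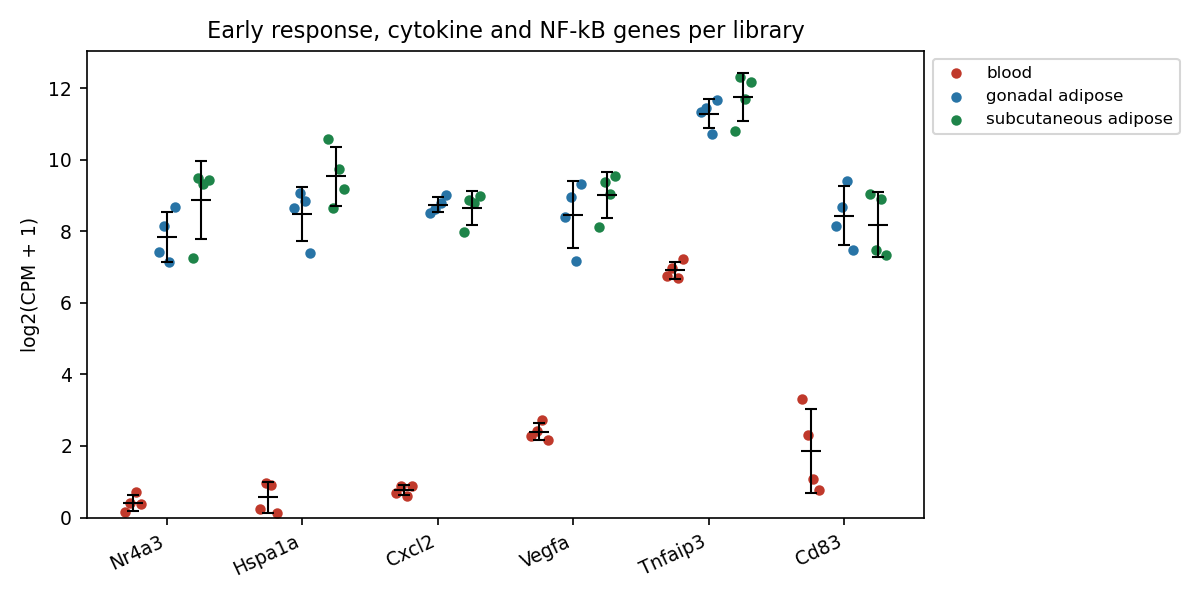
Expression as log2(CPM + 1) on the vertical axis for 6 genes on the horizontal axis; each point is a library, coloured by group, and the black bars give the mean ± SD of the 4 libraries of a group. For each of the 6 genes the adipose libraries lie above the blood libraries, and Cxcl2 averages 0.702 CPM in blood against 430.3 and 416.4 CPM in gonadal and subcutaneous adipose.

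On the eosinophil identity list 11 of 26 genes fell and 3 rose in gonadal adipose (11 and 5 adjusted over the list alone), and 5 rose without the subcutaneous library of mouse 2668. The list's adjusted p was 0.0186 by camera, and 0.648 with an estimated correlation. Ear6 fell by 4.21 (log2 fold change -4.21, SE 0.695), Ear10 had -4.64 (SE 0.443), and Ear1 had -3.54 (SE 0.586), or -4.16 without the gonadal library of mouse 2683. These ribonuclease genes are near-identical copies, so the split of reads between them is uncertain. Siglecf, the sort marker, averaged 273.0 ± 44.3 CPM in blood and 340.6 ± 138 CPM in gonadal adipose (SD, n = 4 each, edgeR adjusted p = 0.535). Adgre1, which encodes F4/80, averaged 723.3 ± 83.7 and 875.4 ± 303 CPM (edgeR adjusted p = 0.574). The IL-5 receptor gene Il5ra averaged 121.6 ± 8.65 and 100.9 ± 36.7 CPM (edgeR adjusted p = 0.546). The granule protein genes were low in both groups. Prg2 averaged 3.52 ± 1.71 and 1.01 ± 0.47 CPM and Epx 4.45 ± 2.02 and 4.49 ± 1.86 CPM, with edgeR adjusted p of 0.129 and 0.994. For Prg2 the adjusted p was 0.0493 without the subcutaneous library of mouse 2846, and DESeq2 gave an adjusted p of 0.0494. Itgam, which encodes CD11b, fell from 1905 ± 112 to 985.7 ± 217 CPM (edgeR adjusted p = 0.0152).

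Ptprc, which encodes CD45, and the eotaxin receptor gene Ccr3 had calls that hung on single libraries. Ptprc averaged 3968 ± 338 CPM in blood and 2120 ± 523 CPM in gonadal adipose (SD, n = 4 each, edgeR adjusted p = 0.0171), and its adjusted p was 0.0548 without the blood library of mouse 2771. Ccr3 averaged 1526 ± 127 and 724.8 ± 245 CPM (edgeR adjusted p = 0.0316). With mouse as a block, its adjusted p was 0.0513. Without any one of the 4 blood libraries, or of the gonadal libraries of mice 2846 and 2683, the adjusted p of Ccr3 lay between 0.053 and 0.0742.

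On the trafficking and adhesion list 12 of 27 genes were lower and 3 higher in gonadal adipose, the same counts when adjusted over the list alone. The adjusted p was 0.0206, and 0.537 with an estimated correlation. The chemokine receptor gene Cxcr2 had a log2 fold change of -6.01 (SE 1), or -6.89 without the gonadal library of mouse 2846, and the sphingosine-1-phosphate receptor gene S1pr4 had -3.48 (SE 0.427). The call of this list ended (adjusted p = 0.0588) without the subcutaneous library of mouse 2846 and the blood library of mouse 2807, a pair left out after the data were seen, and without the latter alone (adjusted p = 0.0527). Only 1 gene was higher without the blood library of mouse 2683 or 2668 or the gonadal library of mouse 2846. On the list of tissue-active eosinophil genes 8 of 19 rose and 2 fell (9 and 3 adjusted over the list alone). Its adjusted p was 0.0427, 0.705 with an estimated correlation and 0.0659 without those 2 libraries. It lay between 0.0519 and 0.0827 without the blood library of mouse 2807 or 2771 or the gonadal library of mouse 2846 or 2668, and 1 gene was lower without that blood library of mouse 2771.

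On the lipid list 11 of 30 genes rose and 3 fell (13 and 3 adjusted over the list alone), led by the fatty acid transporter gene Cd36 with a log2 fold change of 5.25 (SE 0.907). For Cd36 it was 5.99 without the blood library of mouse 2807 and 4.26 without the gonadal library of mouse 2683. Cd36 stood at 29.02 CPM in that blood library and 1202 CPM in that gonadal library, the highest values of their groups. The monocyte sums were also highest there in each group, at 1977 and 6608 CPM. Most of these sums came from the fibronectin gene Fn1, at 1576 and 6195 CPM. RNA from other cells as a source of the lipid genes was not tested in either depot. Nor was it for the cholesterol synthesis, remodelling and cell cycle genes below. The triglyceride lipase gene Pnpla2 fell from 113 ± 11.7 to 56.5 ± 10.4 CPM (SD, n = 4 each). The list's adjusted p was 0.0186, and 0.59 with an estimated correlation. Of the lipid genes 7 were higher without the blood library of mouse 2683 or 2668. Only 1 was lower without the blood library of mouse 2771 or 2683, any of the gonadal libraries of mice 2846, 2807 and 2668, or the subcutaneous library of mouse 2807. On the cholesterol synthesis list 10 of 22 genes rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 0.000158, and 0.286 with an estimated correlation), with 6 higher when mouse was a block. Without the blood library of mouse 2771 or the gonadal library of mouse 2846 or 2683, 5 were higher, and 6 without the blood library of mouse 2668. Sc5d, a late enzyme of that pathway, was the one that fell, with -1.61 (SE 0.31). Tissue remodelling and growth factor genes numbered 12 higher and 2 lower of 27 (15 and 4 adjusted over the list alone), with an adjusted p of 0.0027, and 0.215 with an estimated correlation. Without the blood library of mouse 2771, 7 of them were higher. Of 22 cell cycle genes 8 rose and none fell (9 adjusted over the list alone, adjusted p = 0.000127, and 0.384 with an estimated correlation). Between 3 and 5 rose without the blood library of mouse 2683 or 2668 or the gonadal library of mouse 2846, 2807 or 2683. Mcm3, a replication licensing factor, had 2.76 (SE 0.489), and 3.56 without the blood library of mouse 2807.

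The remaining 8 functional lists were not called. Higher and lower members numbered 7 and 3 of 32 for hypoxia and glycolysis, 3 and 1 of 45 for oxidative phosphorylation and 4 and 4 of 34 for interferon response. They numbered 2 and 4 of 73 for ribosomal proteins, 7 and 6 of 27 for survival and apoptosis and 10 and 9 of 35 for receptors. For Kruppel-like factors they numbered 2 and 4 of 13, and for antigen presentation 7 and 5 of 21. Adjusted over the list alone, those counts were 8 and 6, 2 and 0, 4 and 4, 0 and 3, 10 and 8, 12 and 12, 2 and 4, and 11 and 6, in the same order. Ribosomal protein genes were called lower without the gonadal library of mouse 2683 (12 genes lower, adjusted p = 0.00225, and 0.734 with an estimated correlation). Higher and lower genes numbered 5 and 6 for receptors and 4 and 2 for hypoxia without the blood library of mouse 2771, and 1 and 2 for interferon response without that of mouse 2683. With mouse as a block, interferon response genes numbered 1 higher and 2 lower and antigen presentation genes 3 lower, and 6 hypoxia genes were lower without the subcutaneous library of mouse 2846. The purinergic receptor gene P2rx7 rose by 4.16 (SE 0.471) on the log2 scale, and Bcl2a1b, an anti-apoptotic gene with near-identical copies, by 4.38 (SE 0.587). Ptgdr2, the prostaglandin D2 receptor gene of eosinophils, had -2.72 (SE 0.387).

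Markers of other cells differed between gonadal adipose and blood as well. On the macrophage list 11 of 18 genes rose and none fell (13 adjusted over the list alone, adjusted p = 5.66e-07, and 0.502 with an estimated correlation). The list's summed expression was 502 ± 179 CPM in blood and 2400 ± 1356 CPM in gonadal adipose (SD, n = 4 each). The mannose receptor gene Mrc1 averaged 39.4 ± 61.8 and 469.0 ± 292 CPM (edgeR adjusted p = 0.0512, and 0.0419 with mouse as a block). Without the blood library of mouse 2807, in which Mrc1 stood at 131 CPM, its adjusted p was 0.00524. On the list of adipose fibroblast and progenitor genes 13 of 16 rose and none fell (13 and 1 adjusted over the list alone, adjusted p = 5.66e-07, and 0.488 with an estimated correlation). The neutrophil list fell, with 9 of 10 genes lower in gonadal adipose (9 adjusted over the list alone, adjusted p = 1e-08, and 0.0127 with an estimated correlation). With mouse as a block the adjusted p with an estimated correlation was 0.18, and without the subcutaneous library of mouse 2846 and the blood library of mouse 2807 it was 0.0598. Its sum was 2897 ± 580 CPM in blood and 266 ± 101 CPM in gonadal adipose, most of it from Retnlg, a resistin-like gene (2582 ± 493 and 257.0 ± 96.4 CPM). B cell genes fell for 10 of 14 and T cell genes for 7 of 15 (11 and 7 adjusted over the list alone), with adjusted p of 2.32e-05 and 0.00122, and 0.488 and 0.53 with an estimated correlation. Of the T cell genes 3 were lower without the blood library of mouse 2807, alone or with the subcutaneous library of mouse 2846, and 4 without the gonadal library of mouse 2846, 2807 or 2683 or the subcutaneous library of mouse 2807. Hdc, the histamine-forming enzyme shared by mast cells, basophils and other granulocytes, had a log2 fold change of 4.33 (SE 0.526).

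In other-cell lists of gonadal adipose against blood, higher and lower members numbered 3 and 0 of 11 for dendritic cells, 1 and 1 of 11 for monocytes and 4 and 1 of 9 for adipocytes (adjusted p = 0.09, and without the subcutaneous library of mouse 2846 0.0421, or 0.424 with an estimated correlation). They numbered 3 and 0 of 9 for endothelial cells (adjusted p = 0.0497, 0.694 with an estimated correlation, 0.11 with mouse as a block, and 5 genes higher without the subcutaneous library of mouse 2846) and 0 and 3 of 7 for erythroid cells. The endothelial call also ended (adjusted p of 0.0517 to 0.105) without the blood library of mouse 2683 or 2668, the gonadal library of mouse 2846, 2807 or 2683 or the subcutaneous library of mouse 2807 or 2771. Erythroid genes were called without the blood library of mouse 2807 (6 genes lower, adjusted p = 0.0371, and 0.572 with an estimated correlation), and none was lower without the blood library of mouse 2771 or any 1 of the 8 adipose libraries. For mast cells and basophils they were 1 and 0 of 2, for platelets 1 and 0 of 2 and for mesothelial cells 1 and 1 of 3. None of 7 NK and ILC, 4 skeletal muscle or 1 epithelial genes passed the threshold. Among the erythroid genes, Hba-a1 and Hba-a2 had edgeR adjusted p of 0.048 and 0.049, which were 0.761 and 0.666 without the blood library of mouse 2771 and 0.419 and 0.375 with mouse as a block. Both calls also ended without any 1 of the gonadal or subcutaneous libraries (adjusted p of 0.0508 to 0.131), and that of Hba-a2 ended without the blood library of mouse 2668 (adjusted p = 0.0515).

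Several genes with the largest changes had almost no reads in blood. Dcstamp, a fusion protein of myeloid cells, and Pdk4, a kinase that restrains pyruvate use, had 0 counts over the 4 blood libraries. Against a floor of 3 counts over the group, with counts pooled over the libraries of a group, Dcstamp was at least 1572-fold higher and Pdk4 at least 642-fold higher in gonadal adipose. Without the gonadal library of mouse 2683 the bounds were 882-fold and 225-fold. Dcstamp and Pdk4 stood highest in that library, at 108.2 and 53.52 CPM. The monocyte sum was also highest there, at 6608 CPM, of which Fn1 held 6195 CPM. The complement gene C7 had 1 count in blood, a ratio of 1748 (95% counting interval 313 to 69075), and the matrix-associated gene Aebp1 had 2, a ratio of 943 (261 to 7793). Igfbp5 also had 2, a ratio of 675 (187 to 5581), which was 158 without the gonadal library of mouse 2807. All counts of these 3 genes in blood came from the library of mouse 2771, and without it they were at least 422-fold, 456-fold and 326-fold higher. The adjusted p of C7, Aebp1 and Igfbp5 were 0.133, 0.0624 and 0.167 with mouse as a random effect in limma-voom. RNA from other cells as a source of Dcstamp, Pdk4, C7, Aebp1 or Igfbp5 was not tested.

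In all, 2372 genes were higher and 1780 lower in gonadal adipose than in blood (edgeR's quasi-likelihood test, 15367 genes tested, Benjamini-Hochberg adjusted p under 0.05). With mouse as a block, 1862 genes were higher and 1415 lower. Without the blood library of mouse 2771, 2683 or 2668 the higher genes numbered 1546, 1554 and 1564. With limma-voom's sample weights the counts were 3614 and 2870, and with a log2 fold change of at least 1 the lower genes numbered 1028.

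The second comparison set subcutaneous adipose against blood. Here too early response genes stood higher, as did many cytokine and chemokine genes (for that list, adjusted p = 0.127 with an estimated correlation), and Csf3r, Ear1, Ear2, Ear6 and Ear10 stood lower. Nr4a3 (ENSMUSG00000028341) rose by 10.60 (SE 0.736) on the log2 scale and Hspa1a by 10.59 (SE 0.807). Vegfa averaged 554.5 ± 208 CPM (SD, n = 4), 128-fold above blood. Cxcl2 averaged 416.4 ± 115 CPM (SD, n = 4), with a log2 fold change of 9.19 (SE 0.322). The monocyte-attracting chemokine gene Ccl2 had 1 count over the 4 blood libraries and 1569 counts in subcutaneous adipose, a ratio of 2657 (95% counting interval 476 to 105022). Without the blood library of mouse 2683, which held that count, Ccl2 was at least 667-fold higher against a floor of 3 counts over the group. Csf3r averaged 18.5 ± 7.76 CPM (SD, n = 4), with a log2 fold change of -4.13 (SE 0.379). Ear1, Ear10, Ear6 and Ear2 had log2 fold changes of -4.62 (SE 0.637), -4.61 (SE 0.449), -4.21 (SE 0.714) and -3.77 (SE 0.641), the last being -4.65 without the subcutaneous library of mouse 2846. The acute phase gene Hp, for haptoglobin, had -4.59 (SE 0.697), and -5.84 without the subcutaneous library of mouse 2771.

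On the immediate early list 32 of 34 genes rose and none fell (33 adjusted over the list alone), with a median of 3.53 (adjusted p = 3.17e-27, and 0.000374 with an estimated correlation). For NF-kB and TNF response 15 of 27 rose and 1 fell (20 and 1 adjusted over the list alone, adjusted p = 1.3e-09, and 0.0312 with an estimated correlation). The latter was 0.0533 without the gonadal library of mouse 2683 and 0.0645 without the subcutaneous library of mouse 2807. Tnfaip3 rose by 4.95 (SE 0.362) and Cd83 by 6.52 (SE 0.896), or 7.38 without the blood library of mouse 2807. For cytokines and chemokines 21 of 31 rose and 4 fell (22 and 4 adjusted over the list alone, adjusted p = 9.93e-08, and 0.127 with an estimated correlation). Of the cytokine genes 2 were lower with mouse as a block, and also without the blood library of mouse 2771, 2683 or 2668 or the subcutaneous library of mouse 2771. Without the subcutaneous library of mouse 2846, 2 were lower and the adjusted p with an estimated correlation was 0.024. The lymphocyte-attracting cytokine gene Il16 had -2.32 (SE 0.236). On the eosinophil identity list 3 of 26 genes rose and 11 fell, the same counts when adjusted over the list alone (adjusted p = 0.0136, and 0.704 with an estimated correlation). Gata2, a transcription factor of eosinophil, basophil and mast cell lineages, rose by 3.54 (SE 0.428). Siglecf averaged 307.0 ± 142 CPM, Adgre1 820.7 ± 368, Il5ra 120.5 ± 44.7, Prg2 1.38 ± 1.24 and Epx 3.95 ± 3.24 CPM in subcutaneous adipose (SD, n = 4). Their edgeR adjusted p were 0.748, 0.711, 0.984, 0.268 and 0.916.

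Itgam fell to 919.6 ± 316 CPM (SD, n = 4, edgeR adjusted p = 0.00972). Ptprc averaged 2202 ± 591 CPM (edgeR adjusted p = 0.023). Its adjusted p lay between 0.0518 and 0.0673 without the blood library of mouse 2771, 2683 or 2668 or the subcutaneous library of mouse 2846 or 2771. Ccr3 averaged 704.3 ± 340 CPM (edgeR adjusted p = 0.0275), and 0.051 to 0.0746 without the blood library of mouse 2807, 2771 or 2683 or the subcutaneous library of mouse 2846 or 2771.

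**Figure D3:**
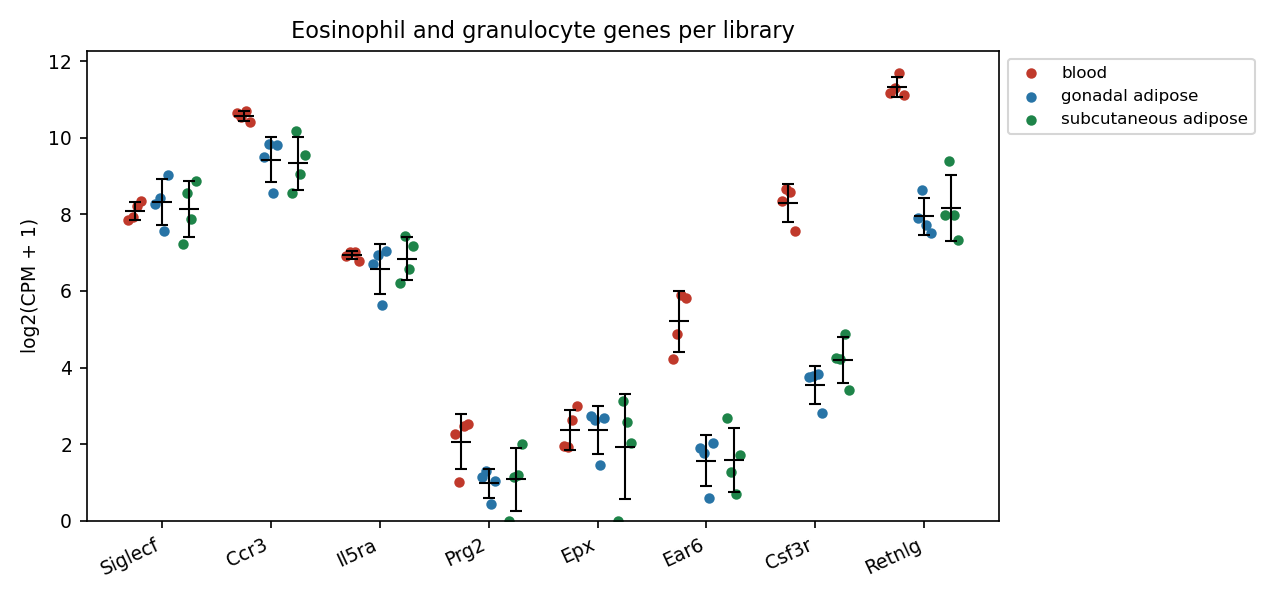
Expression as log2(CPM + 1) on the vertical axis for 8 genes on the horizontal axis; each point is a library, coloured by group, and the black bars give the mean ± SD of the 4 libraries of a group. Csf3r averages 325.1 CPM in blood, 11.1 CPM in gonadal and 18.5 CPM in subcutaneous adipose, while the Siglecf ranges overlap between groups.

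Ribosomal protein genes were lower in subcutaneous adipose for 14 of 73 and higher for none (13 adjusted over the list alone), with a median log2 fold change of -0.35 and an adjusted p of 0.000635, and 0.729 with an estimated correlation. Lower ribosomal protein genes numbered 26 without the gonadal library of mouse 2683, 8 without the blood library of mouse 2683 and 9 without the subcutaneous library of mouse 2668. Rpl27 had -1.90 (SE 0.45). Cholesterol synthesis genes numbered 7 higher and 1 lower of 22 (8 and 1 adjusted over the list alone, adjusted p = 0.0277, and 0.704 with an estimated correlation). Without the subcutaneous library of mouse 2846 that adjusted p was 0.0544 with 4 genes higher, and 2 genes were higher with mouse as a block. It was 0.0516 without the blood library of mouse 2771. Without that library or the blood library of mouse 2683 or 2668 1 gene was higher, and 4 were without the subcutaneous library of mouse 2807. Remodelling genes numbered 10 higher and 4 lower of 27 (11 and 4 adjusted over the list alone, adjusted p = 0.0311, and 0.537 with an estimated correlation). That adjusted p was 0.0602 and 0.0526 without the subcutaneous library of mouse 2771 or 2807. Without the former, 6 genes were higher and 2 lower, and without the blood library of mouse 2771 or 2668 5 and 6 were higher. Of these genes 2 were lower without the blood library of mouse 2683. Cell cycle genes numbered 6 higher and 0 lower of 22 (6 adjusted over the list alone, adjusted p = 0.0413, and 0.704 with an estimated correlation). This call ended without the blood library of mouse 2683 or 2668 or the subcutaneous library of mouse 2807 or 2771, with adjusted p of 0.0571 to 0.194, and 3 genes were higher without the blood library of mouse 2683 or 2668 or the subcutaneous library of mouse 2771. Trafficking genes numbered 2 higher and 8 lower of 27 (4 and 12 adjusted over the list alone), with an adjusted p of 0.0311, 0.704 with an estimated correlation, 0.052 without the subcutaneous library of mouse 2846 and 0.0548 without the blood library of mouse 2807. Only 1 trafficking gene was higher without the blood library of mouse 2771 or 2668 or the subcutaneous library of mouse 2807. The chemokine receptor gene Cxcr4 was 1.59 (SE 0.376) higher on the log2 scale and S1pr4 had -2.48 (SE 0.409).

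Lipid genes numbered 5 higher and 2 lower of 30 (4 and 1 adjusted over the list alone). That list was not called (adjusted p = 0.08), though it was with mouse as a block (adjusted p = 0.022) and without both the subcutaneous library of mouse 2846 and the blood library of mouse 2807 (adjusted p = 0.0329). With an estimated correlation the adjusted p of these lipid calls were 0.66 and 0.58. Lipid genes were also called without the blood library of mouse 2807 (8 genes higher, adjusted p = 0.03, and 0.644 with an estimated correlation) or the gonadal library of mouse 2683 (adjusted p = 0.0468, and 0.59 with an estimated correlation). Dgat1, an enzyme of triglyceride synthesis, rose by 4.24 (SE 0.536) and Cd36 by 3.82 (SE 0.85), or 4.56 without the blood library of mouse 2807. Tissue-active eosinophil genes numbered 8 higher and 2 lower of 19 (8 and 2 adjusted over the list alone), with an adjusted p of 0.099, and 0.0213 without the subcutaneous library of mouse 2846 (adjusted p = 0.66 with an estimated correlation). Hypoxia and glycolysis genes numbered 7 higher and 6 lower of 32, oxidative phosphorylation 2 and 2 of 45 and interferon response 3 and 3 of 34. Survival and apoptosis genes numbered 7 and 6 of 27, receptors 9 and 9 of 35, Kruppel-like factors 2 and 4 of 13 and antigen presentation 6 and 3 of 21. None of those 7 lists was called, though antigen presentation was without both of those libraries (adjusted p = 0.0329, and 0.58 with an estimated correlation) and without the blood library of mouse 2807 alone (adjusted p = 0.0465, and 0.654 with an estimated correlation). Adjusted over the list alone, the counts were 7 and 8, 2 and 2, 3 and 3, 8 and 8, 12 and 12, 3 and 4, and 6 and 4, in the same order. Hypoxia genes numbered 6 and 10 without the subcutaneous library of mouse 2668, and antigen presentation genes 4 and 1 without the blood library of mouse 2771, 2683 or 2668. The costimulatory genes Cd80 and Cd86 rose by 2.49 (SE 0.48) and 2.48 (SE 0.427).

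Macrophage genes rose for 11 of 18 in subcutaneous adipose (14 adjusted over the list alone, adjusted p = 1.12e-07, and 0.429 with an estimated correlation), with a sum of 3089 ± 1576 CPM (SD, n = 4). Mrc1 averaged 656.9 ± 344 CPM (edgeR adjusted p = 0.0349), and its adjusted p lay between 0.0505 and 0.0917 without the blood library of mouse 2771 or 2683, the gonadal library of mouse 2683 or 2668 or the subcutaneous library of mouse 2846 or 2771. Fibroblast and progenitor genes rose for 11 of 16 and fell for none, or for 1 without the gonadal library of mouse 2683 (14 and 1 adjusted over the list alone, adjusted p = 1.42e-07, and 0.429 with an estimated correlation). Their sum was 5227 CPM in the subcutaneous library of mouse 2846 and 455 to 633 CPM in the other subcutaneous libraries. Neutrophil genes fell for 9 of 10 (9 adjusted over the list alone, adjusted p = 1.06e-07, and 0.0195 with an estimated correlation). With mouse as a block the adjusted p with an estimated correlation was 0.211, and without the subcutaneous library of mouse 2846 and the blood library of mouse 2807 it was 0.0676. Retnlg averaged 333.5 ± 227 CPM, with a log2 fold change of -2.95 (SE 0.418), and -3.54 without the subcutaneous library of mouse 2807. T cell genes rose for 5 of 15 (7 adjusted over the list alone, adjusted p = 0.000626, and 0.464 with an estimated correlation), and 1 of 15 passed the threshold without the subcutaneous library of mouse 2846, and 2 with mouse as a block. None or 1 passed without the blood library of mouse 2771, 2683 or 2668 or the subcutaneous library of mouse 2771, and 3 without the subcutaneous library of mouse 2807.

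Other-cell lists of subcutaneous adipose against blood held 3 higher and 0 lower of 11 dendritic cell genes, 0 and 1 of 11 monocyte genes and 0 and 1 of 14 B cell genes. The B cell list had an adjusted p of 0.0543, and 0.0266 with mouse as a block (0.525 with the block and an estimated correlation). It lay between 0.00779 and 0.0483 without the blood library of mouse 2683 or 2668, the gonadal library of mouse 2846 or 2807 or the subcutaneous library of mouse 2771 (0.478 to 0.576 with an estimated correlation). Dendritic cell genes were called without the blood library of mouse 2807 or the subcutaneous library of mouse 2668 (adjusted p = 0.0301 and 0.047, and 0.385 and 0.413 with an estimated correlation). Without the latter, endothelial and NK and ILC genes were called too (adjusted p = 0.0196 and 0.0352, and 0.413 and 0.275 with an estimated correlation). Adipocyte genes numbered 5 and 1 of 9 (adjusted p = 0.0356, 0.429 with an estimated correlation 0.0503 without the subcutaneous library of mouse 2846 and the blood library of mouse 2807, and 0.06 without the subcutaneous library of mouse 2807). Endothelial genes numbered 4 and 0 of 9, with 1 higher with mouse as a block. Mast cell and basophil genes numbered 1 and 0 of 2, platelet genes 1 and 0 of 2 and mesothelial genes 1 and 1 of 3. None of 7 NK and ILC, 7 erythroid, 4 skeletal muscle or 1 epithelial genes passed the threshold.

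The extracellular matrix genes Col5a2, Mmp2 and Eln and the receptor gene Notch3 had 0 counts over the 4 blood libraries. Against a floor of 3 counts over the group they were at least 447-fold, 448-fold, 270-fold and 292-fold higher in subcutaneous adipose, with counts pooled over the libraries of a group. In the subcutaneous library of mouse 2846, where the fibroblast and progenitor sum was 5227 CPM (455 to 633 CPM in the others), these genes stood highest. Without it the bounds for Col5a2, Mmp2, Eln and Notch3 were 239-fold, 312-fold, 105-fold and 130-fold. With mouse as a block the 4 genes' edgeR adjusted p were 0.0708, 0.0634, 0.114 and 0.123. Col5a3 and C7 had ratios of 1007 (95% counting interval 278 to 8323) and 1602 (287 to 63347). The ratios were 300 and 999 without the subcutaneous library of mouse 2846. The ratio of Col5a3 was 1575 without the blood library of mouse 2807, and C7 was at least 387-fold higher without the blood library of mouse 2771, which held its only count in blood. Their adjusted p were 0.0952 and 0.169 with mouse as a random effect in limma-voom.

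In all, 2366 genes were higher and 1755 lower in subcutaneous adipose than in blood (edgeR's quasi-likelihood test, adjusted p under 0.05). With mouse as a block, 1588 genes were higher and 1322 lower. Without the blood library of mouse 2683 or 2668 the higher genes numbered 1566 and 1569, and with a log2 fold change of at least 1 the lower genes numbered 912.

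Both adipose comparisons used the same blood libraries. Across the 15367 genes, which are not independent replicates, their log2 fold changes correlated with r = 0.874 and a covariance of 3.005. Simulated groups with no change, set against shared controls in the same way, gave a mean r of 0.489 and a mean covariance of 0.283. With the blood libraries split, 2 for each depot, the mean over 6 splits was r = 0.721 with a covariance of 3.045. Of the called genes, 1806 were higher in both depots, where independent lists would share 365.2, and 1261 were lower in both, where they would share 203.3. Those expected numbers leave out the shared blood libraries. With mouse as a block, 1322 genes were higher in both (192.4 expected) and 985 lower in both (121.7 expected). With the blood libraries split, a mean of 609.7 genes were higher in both (77.54 expected) and 569.5 lower in both (56.01 expected). The simulated unchanged groups shared 0, but they called at most 1 gene per direction and comparison, so that 0 is no measure of overlap. One gene was called in opposite directions.

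**Figure D4:**
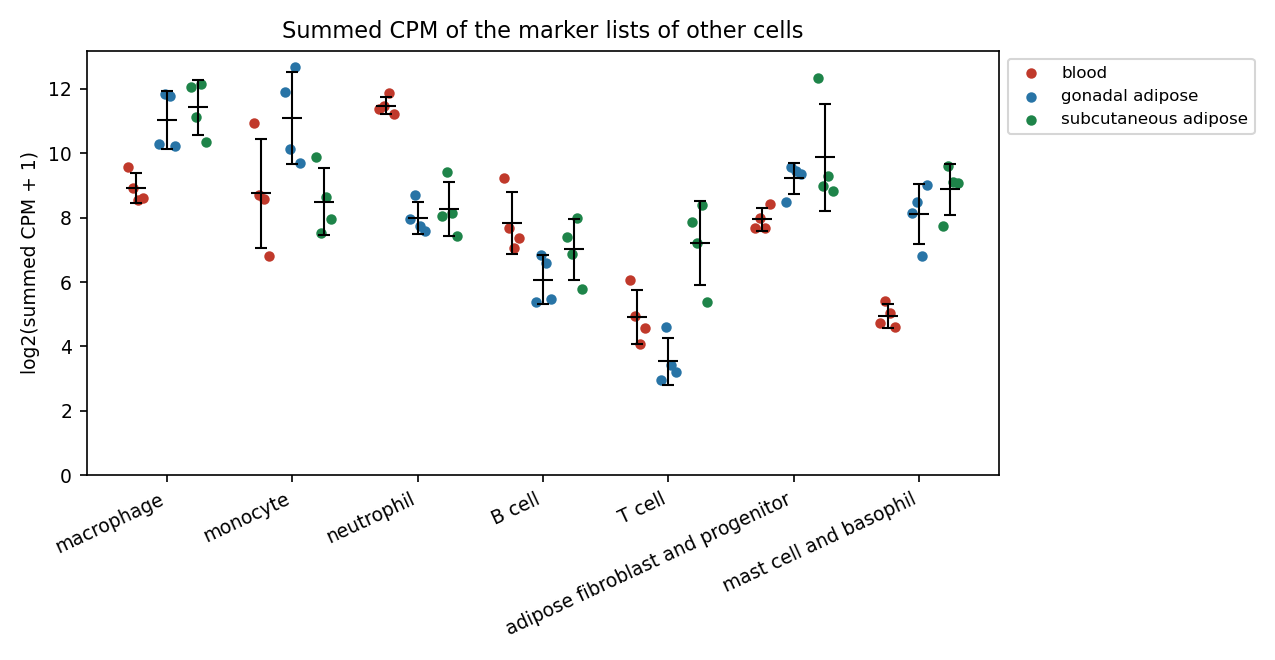
Summed expression of marker genes as log2(summed CPM + 1) on the vertical axis for 7 lists of other cells on the horizontal axis; each point is a library, coloured by group, and the black bars give the mean ± SD of the 4 libraries of a group. The neutrophil sum averages 2897 CPM in blood and 266 CPM in gonadal adipose, and the fibroblast sum reaches 5227 CPM in the subcutaneous library of mouse 2846. The monocyte sum averages 722, 3103 and 444 CPM in blood, gonadal and subcutaneous adipose, of which Fn1 holds 519.4, 2819 and 251.3 CPM.

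The third comparison set the depots against each other. One gene was called: Lef1, a transcription factor prominent in T lymphocytes (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356 in mm10). It averaged 0.0665 ± 0.0773 CPM in gonadal and 20.3 ± 13.2 CPM in subcutaneous adipose (SD, n = 4 each). Its log2 fold change was -8.23 (SE 0.959, edgeR adjusted p = 0.0185), or -8.83 without the gonadal library of mouse 2807, and in blood it averaged 5.85 ± 1.62 CPM. Its adjusted p was 0.131 with mouse as a block. The adjusted p lay between 0.0552 and 0.118 without the blood library of mouse 2771, the gonadal library of mouse 2846, 2683 or 2668 or the subcutaneous library of mouse 2807 or 2771. T cell genes as a list were lower in gonadal adipose, with a median log2 fold change of -4.82 (adjusted p = 5.53e-28, and 0.028 with an estimated correlation). None of the 15 passed the threshold over all genes, and 13 did adjusted over the list alone. The adjusted p with an estimated correlation was 0.0506 to 0.0763 without the gonadal library of mouse 2807, 2683 or 2668 or the subcutaneous library of mouse 2846, 2807 or 2771, 0.0862 without the subcutaneous library of mouse 2846 and the blood library of mouse 2807, and 0.133 with mouse as a block. Without the subcutaneous library of mouse 2668, 2 T cell genes passed the threshold over all genes. The list's sum was 12 ± 7.58 CPM in gonadal and 188 ± 124 CPM in subcutaneous adipose.

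The immediate early list was lower in gonadal than in subcutaneous adipose, with a median log2 fold change of -0.47 (adjusted p = 1.14e-07, and 0.04 with an estimated correlation). None of its 34 genes passed the threshold over all genes, and 3 did adjusted over the list alone. The adjusted p with an estimated correlation was 0.0952 with mouse as a block and 0.12 without the subcutaneous library of mouse 2846 and the blood library of mouse 2807. It lay between 0.0539 and 0.16 without the blood library of mouse 2807, 2771 or 2683, the gonadal library of mouse 2846, 2683 or 2668 or any 1 of the subcutaneous libraries. Without the gonadal library of mouse 2807, 1 gene of the list was lower. Camera also placed 4 lists higher in gonadal adipose: oxidative phosphorylation (median 0.34, adjusted p = 3.34e-06), ribosomal proteins (median 0.31, adjusted p = 1.51e-06), cell cycle (median 0.59, adjusted p = 0.000372) and cholesterol synthesis (median 0.53, adjusted p = 0.000888). Each had an adjusted p of 0.679 with an estimated correlation, and no member of any of them was called, also when adjusted over the list alone. Without the gonadal library of mouse 2683 the ribosomal protein call ended (adjusted p = 0.0912), and the cell cycle median was 1.19 without the subcutaneous library of mouse 2771. The lipid list had an adjusted p of 0.146, and 0.0373 with mouse as a block (0.832 with the block and an estimated correlation). It was 0.0344 without the subcutaneous library of mouse 2771 (0.745 with an estimated correlation). B cell genes (median -2.25, adjusted p = 3.32e-06) and NK and ILC genes (median -1.93, adjusted p = 0.0163) were lower in gonadal adipose by camera, both with an adjusted p of 0.474 with an estimated correlation. The NK and ILC call ended (adjusted p of 0.059 to 0.161) without the gonadal library of mouse 2668 or the subcutaneous library of mouse 2846, 2807 or 2771. Its adjusted p with an estimated correlation was 0.0474 without the subcutaneous library of mouse 2668, and its median was -2.95 without the gonadal library of mouse 2807. Adjusted over the list alone, 6 of the 14 B cell genes were lower. With all libraries none of the other lists was called. Without the subcutaneous library of mouse 2846, endothelial genes (median 1.29, adjusted p = 5.18e-05) and fibroblast and progenitor genes (median 0.83, adjusted p = 0.00747) were higher in gonadal adipose, where all libraries gave medians of -1.09 and -0.67. Their adjusted p with an estimated correlation were then 0.204 and 0.535. Interferon response genes were called lower in gonadal adipose without the blood library of mouse 2668, the gonadal library of mouse 2683 or the subcutaneous library of mouse 2807 or 2668 (adjusted p of 0.00985 to 0.0391, and 0.608 to 0.803 with an estimated correlation). Dendritic cell genes were called lower without the gonadal library of mouse 2846 or the subcutaneous library of mouse 2668 (adjusted p = 0.0393 and 0.0326, and 0.597 and 0.59 with an estimated correlation). Hypoxia genes were called higher without the latter (adjusted p = 0.0452, and 0.675 with an estimated correlation). Cytokine genes were lower in gonadal adipose without both the subcutaneous library of mouse 2846 and the blood library of mouse 2807 (adjusted p = 0.046, and 0.653 with an estimated correlation). Fn1, the fibronectin gene, had a log2 difference of 3.49 (SE 1.21, edgeR adjusted p = 0.498).

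In this comparison edgeR called 0 genes higher and 1 lower in gonadal adipose, with 1234 genes at an unadjusted p under 0.05. With mouse as a block it called 0 and 0 genes. DESeq2 called 42 higher and 110 lower, and limma-voom with sample weights called 0. The lower genes numbered 7 without the subcutaneous library of mouse 2668, and 2 without the subcutaneous library of mouse 2846 or the gonadal library of mouse 2807, which also gave 1 higher. They numbered 0 without any of the 6 libraries whose absence ended the Lef1 call. In simulated data for this comparison, 50% of genes changed 4-fold and 15.2% of genes changed 2-fold were called.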

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

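All tests of explanations in this part were chosen or written down after the results they bear on had been seen, and the genes and sums searched for outlying libraries were also chosen after seeing the data.

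Early response genes were higher in both fat depots than in blood. The list's median log2 fold change was at least 2.88 in both depots under all 4 scalings, where normalization as the cause was taken to give a value below 1. Against blood these scalings kept the median of all genes between -0.058 and 0.097. They could therefore hardly move the list that far, so the choice among them mattered little and normalization as such was not decided. Macrophages of one fixed RNA profile as the whole source would make the called members follow the macrophage sum within depots with a slope of 1. Over the 8 adipose libraries the slope of the members' mean log2 CPM was 0.119 for 31 immediate early genes, 0.0488 for 13 NF-kB genes and 0.107 for 21 cytokine genes. The exact permutation p against a slope of 1 was 0.0104, 0.0104 and 0.0295 (576 permutations). The exact permutation p against a slope of 0 was 0.0417, 0.655 and 0.689. These p-values were not adjusted for the number of lists, so a rise of the immediate early genes with the macrophage sum is not established. These permutations treat the 8 adipose libraries as independent, though mice 2846, 2807 and 2668 each gave a library of both depots. A slope of the mean does not bear on single members. In the subcutaneous libraries of mice 2846, 2807, 2771 and 2668 the macrophage sums were 4257, 2215, 4569 and 1317 CPM. Cd83 stood there at 528.2, 177.3, 475.2 and 159.8 CPM, and Tnfaip3 at 1793, 5080, 3320 and 4637 CPM. Macrophages as part of the source, as the whole source of single members, or with a profile that varies between libraries, stay open. Warm enzymatic digestion cannot be told apart from tissue residence, since the labels give a digestion step for 0 of 4 blood libraries and for all 8 adipose libraries, and a difference between tissues stays open and untested.

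T cell genes were lower in gonadal than in subcutaneous adipose, with a median log2 fold change of -4.82 in a test of the depot difference itself. Dependence on 1 library alone is argued against by the depots' difference in mean log2 CPM of the list. That difference lay beyond 2 SE of 0 without each of the 8 adipose libraries in turn, the only ones that enter it. The value closest to 0 was -3.86 (SE 0.848), without the subcutaneous library of mouse 2771. However, leaving out any 1 of 6 adipose libraries ended the call with an estimated correlation (adjusted p of 0.0506 to 0.0763), as did mouse as a block (0.133). With group means removed, the 15 genes varied together over libraries with a mean pairwise correlation of 0.463, above the range of -0.0484 to 0.137 that held 95% of 10000 random lists, which is consistent with RNA from T cells at varying amounts. The sort for CD11b and Siglec-F should remove T cells, the list summed to only 188 ± 124 CPM in subcutaneous adipose, and a difference between depots in the cells themselves was not tested. Lef1, with a log2 fold change of -8.23 (-8.83 without the gonadal library of mouse 2807), was the gene called between depots, though its adjusted p was 0.131 with mouse as a block and lay between 0.0552 and 0.118 without any 1 of 6 libraries.

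Neutrophil genes were higher in blood than in both depots. If one neutrophil RNA profile were the source in every library, the ratio of Retnlg to S100a8 plus S100a9 would be alike. The log2 ratio was 3.65 ± 0.405 in blood (SD, n = 4) and 6.41 ± 1.65 in adipose (SD, n = 8), a difference of 2.76 (exact permutation p = 0.00808, 495 permutations), with the highest blood value at 4.23 and the lowest adipose value at 5.01. That argues against a single profile as the source of all 3 genes, but the permutations treat 12 libraries from 5 mice as independent. S100a9 was low in adipose, averaging 2.1 CPM in gonadal and 4.63 CPM in subcutaneous libraries. It stood at 0.118 CPM in the gonadal library of mouse 2683, so the adipose ratios are imprecise. Neutrophils of different kinds, or expression by eosinophils, could each remain as part of the source and were not tested.

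The immediate early list differed between the depots with a median log2 fold change of -0.47 (camera adjusted p with an estimated correlation 0.04). That adjusted p was 0.0952 with mouse as a block and 0.0539 to 0.16 without any 1 of 10 libraries, the subcutaneous library of mouse 2846 among them (0.0661), no member was called over all genes and 3 were adjusted over the list alone. Single libraries lay far from the rest of their group for 11 of 117 sets of 4 values, where chance gives about 1 in 20. The subcutaneous library of mouse 2846 held 28% mitochondrial ribosomal RNA (others 5.64% to 8.19%) and 7.12% of reads in retained intron transcripts (others 9.84% to 10.2%). Its fibroblast and progenitor sum was 5227 CPM (others 455 to 633 CPM). The blood library of mouse 2807 held 131 CPM of Mrc1 (others 0.943 to 23.1 CPM), a dendritic cell sum of 98.8 CPM (others 34.4 to 41 CPM), a monocyte sum of 1977 CPM (others 112 to 418 CPM) and a B cell sum of 596 CPM (others 133 to 205 CPM). Fn1 held 1576 CPM of that monocyte sum. In the blood library of mouse 2771 haemoglobin took 0.827% of reads (others 0.00192% to 0.0145%), and the erythroid sum was 8527 CPM (others 46.5 to 177 CPM). Epx stood at 1.73 CPM in the gonadal library of mouse 2683 (others 5.19 to 5.7 CPM), and Csf3r at 6.03 CPM in that of mouse 2668 (others 12.5 to 13.2 CPM).

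Other splits of the libraries were counted for each comparison. Gonadal adipose against blood gave 4152 genes, the highest other split gave 1, and 1 of 35 splits, the real one, gave as many. Subcutaneous adipose against blood gave 4121 genes, the highest other split gave 1, and again 1 of 35 gave as many. For both, no other split came near the real count, and 1 of 35 is the smallest share these splits allow. The 35 splits ignore that libraries of the same mouse are paired. Between depots the real split gave 1 gene, the highest other gave 16, and 2 of 35 splits gave as many, so chance cannot be excluded. That split called several times the real count, which points to a structure of the samples. It set the gonadal libraries of mice 2846 and 2668 and the subcutaneous libraries of mice 2807 and 2668 against the other adipose libraries. Their macrophage sums were 1198 to 2215 CPM, against 3502 to 4569 CPM in the others. Whether the amount of RNA from other cells underlies those calls was not tested. In each comparison 7 other splits parted 3 mouse pairs as the real one did, and the most genes they gave was 0. Those 7 are too few for a share under 0.05, so with the pairing kept these splits cannot exclude chance.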

How the results depend on the processing

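Of the alternatives, leaving out both the subcutaneous library of mouse 2846 and the blood library of mouse 2807, and the list tests, floors, ratios and gene families without each library in turn, were chosen after seeing the data. Among named genes 5628 results kept their side of the threshold, 277 lost a call and 46 gained one. Results called in neither fit count as kept, also where their direction changed. No named gene with a call in either fit reversed. Among lists 356 results kept their side of the threshold in the same sense, 39 lost a call, 11 gained one and 2 reversed. In gonadal against blood 48 of 76 called named genes were called in every alternative that tested them, in subcutaneous against blood 50 of 73, and between depots 0 of 1. Some alternatives left out some of the named genes. Genes lower in gonadal than subcutaneous adipose numbered 0 with the mouse number as a replicate block (fixed effect, or random effect in limma-voom), 0 with sample weights, 0 with only the libraries compared and 0 without both outlying libraries. The edgeR count there was 1, with 1234 genes at an unadjusted p under 0.05. DESeq2 gave 42 higher and 110 lower. Sample weights gave 3614 higher and 2870 lower in gonadal adipose than blood. A log2 fold change of at least 1 left 1028 and 912 lower genes in gonadal and subcutaneous adipose against blood. With an estimated correlation 2, 2 and 1 functional lists were called in the 3 comparisons, besides the neutrophil list in both comparisons with blood and the T cell list between depots. Of these, the neutrophil (adjusted p = 0.0598 and 0.0676), T cell (0.0862) and immediate early depot calls (0.12) ended without both outlying libraries. Without each library in turn, 13 of 16, 9 of 14 and 6 of 8 camera calls held in the 3 comparisons, and 2 of 3, 2 of 3 and 0 of 2 with an estimated correlation. Leaving out 1 library gave 1546 to 2925 genes higher in gonadal adipose than blood, 1566 to 2495 higher in subcutaneous adipose than blood, and 0 to 1 higher and 0 to 7 lower between depots. The correlation of the adipose comparisons was 0.822 to 0.884 without 1 library and 0.721 with the blood libraries split. The fibroblast and progenitor list turned between depots, with a median of 0.8263 without the subcutaneous library of mouse 2846 and 0.8269 without both outlying libraries; that library's fibroblast sum was 5227 CPM. For the other changes the cause was not tested, except that splitting or leaving out libraries leaves fewer samples and a fold limit is stricter by construction. Apart from the calls given beside their results, single-list calls with the fixed block were as without it. Scaling by library size only shifted the median of all genes between depots to 0.127, and the medians of the tissue-active, trafficking, receptor and antigen presentation lists, none of them called between depots, changed sign with the scaling. Against blood the same held for ribosomal protein, dendritic cell and monocyte lists in gonadal adipose and for survival and receptor lists in subcutaneous adipose. The depth of 4379954 reads limits what the subcutaneous library of mouse 2846 shows for genes of low abundance.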

Other observations

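The gene families described here were grouped by the stem of their symbols and tested after seeing the data. Gimap genes, GTPases of lymphocytes and other immune cells, were lower in gonadal adipose than in blood for 9 of 9 members, with a median log2 fold change of -2.95 (camera adjusted p = 0.000965, and 0.965 with an estimated correlation). Of these, 6 were lower with mouse as a block or without the blood library of mouse 2807. Between depots their median was -3.55, and -4.22 without the gonadal library of mouse 2668, with no member called by edgeR and 1 called without the subcutaneous library of mouse 2668 (camera adjusted p = 6.68e-10, and 0.664 with an estimated correlation). T and B cell lists moved the same way, with medians of -2.42 and -3.69 in gonadal adipose against blood and -4.82 and -2.25 between depots (for B cell genes against blood, -2.63 without the blood library of mouse 2807). Heat shock 70 genes of the Hspa family were higher than in blood for 8 of 12 members in gonadal and 8 of 12 in subcutaneous adipose, with medians of 1.67 and 1.70 (camera adjusted p = 0.000854 and 6.28e-05, and 0.404 and 0.195 with an estimated correlation). Collagen genes were higher for 14 and lower for 2 of 26 in gonadal adipose, and higher for 15 and lower for 1 in subcutaneous adipose (camera adjusted p = 0.00102 and 0.00012, and 0.965 and 0.95 with an estimated correlation). Without the subcutaneous library of mouse 2846, 13 were higher in subcutaneous adipose. Fibroblast and progenitor genes, some of them collagens, were higher for 13 of 16 in gonadal and 11 of 16 in subcutaneous adipose, and their sum was 5227 CPM in the subcutaneous library of mouse 2846 against 455 to 633 CPM in the other subcutaneous libraries. Of 406 families tested, 0 were called with an estimated correlation.

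Reads in lincRNA transcripts made up 4.8% ± 0.397 in gonadal, 4.63% ± 0.487 in subcutaneous adipose and 3.3% ± 0.337 in blood (SD, n = 4 each). The exact permutation p was 0.0286 for each depot against blood, the smallest that 70 splits allow, and the adjusted p over 27 tests was 0.257.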
